A study of Arabidopsis thaliana with 10 samples.

How the data were processed

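Leaf RNA of Arabidopsis thaliana was measured on 10 Affymetrix arrays of 22810 probe sets. The arrays form 5 groups of 2: wild type at stage 3.9, and wild type, NahG, ein2 and coi1 at stage 6.0. Per the submitters' processing notes the authors made the deposited intensity values with MAS5, whose version is not given in the sources used here. The values are signals on a linear scale, and each deposited array has a 2% trimmed mean of 100 over all probe sets. The table holds no detection calls. The 2 arrays of each wild type group carry different stock codes, so their spread includes any difference between stocks. For the other groups the labels do not say whether the arrays came from separate plants. The p-values measure spread between these samples, which may be technical in those groups.

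Each array was rescaled to a 2% trimmed mean of 100 over the probe sets that are not controls. The 64 Affymetrix control probe sets were left out of the tests. Probe sets with a signal of 50 or more on at least 2 arrays were kept, which left 12184. Changes were fitted on log2(signal + 16) with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3, over all 10 arrays and 5 groups, with 5 residual and 5.74 prior degrees of freedom. All gene tests are moderated t tests of limma, adjusted by Benjamini-Hochberg within a comparison, and a probe set passed at an adjusted p under 0.05. The median standard error of a log2 difference between 2 groups was 0.21, and a group of 2 arrays sets that precision. The added 16 shrinks the fold of genes with low signals. Values after ± are standard errors of the log2 difference, or standard deviations where so marked. The stock difference was fitted as a term for the 4 wild type arrays. Tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

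Gene names came from the platform's probe table, with current symbols from a table of the TAIR10.1 annotation used for names only. No sequence build was used and no coordinates are given. One gene was named for 13513 probe sets, several for 503 and none for 8730. Of the tested probe sets 6452 name 1 gene, 265 several and 5467 none. Probe sets with no named gene were counted, not named. Where several probe sets name the same gene, as for 34 genes, the one of highest mean signal was used, and 0 such genes had calls in opposite directions.

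The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The lists hold 341 genes, of which 61 have a named probe set and 53 were tested. Genes of the lists called measured are those tested, and most others are unnamed here, not shown to be absent from the arrays. A named probe set was found for 1 of 30 genes of the salicylic acid list and 3 of 32 of the jasmonate list. It was found for 4 of 29 of the ethylene list and 5 of 22 senescence-associated genes. SAG12, PR1 and VSP2 were among the genes not tested. Lists with at least 3 tested genes (6 of 20) were tested with camera in limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry, which tests movement in 1 direction only. Members were also counted after adjustment over the list alone. The markers of floral organs, dividing cells and vascular tissue have 0 named probe sets, the trichome markers 1, which was not tested, and the guard cell markers 2, of which GASA9 was tested. Gene families of at least 5 tested members were formed from the letters of gene symbols, and the plastid genome was added as a group.

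Named genes are the 8 highest and 8 lowest changes per main comparison among probe sets that passed, name 1 gene and do not overlap between groups. Where fewer passed, those that passed were named with the 3 of smallest p in each direction. Up to 3 members past the threshold were named per list, or 2 as values where none passed, plus a fixed set of genes. For genotype pairs and stocks the 3 highest and 3 lowest were named. Other members of the lists given as values were chosen after their values were seen.

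The stage 6.0 wild type arrays enter several contrasts. Covariances were therefore compared with 100 simulated sets without effects, and the stage change of each stock was set against the genotype difference from the array of the other stock. Wild type arrays of the same stock at the 2 stages showed little pairing (correlation of their deviations from the group means 0.0762), and with pairing as a replicate block the stage count was 4831 against 4560. The whole procedure was tested on simulated data with 200 changed probe sets. It recovered 59 to 63% of changes of log2 1 in the stage and genotype comparisons and 99 to 100% of changes of log2 2, with 4.24 to 7.02% false calls. It called 3 of 3 simulated list shifts of 0.5 and 0 of 39 lists without a shift. These list counts are not shown to hold where the genes of a list vary together in leaves. With an estimated correlation none of the list shifts of the data passed.

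The alternatives were added constants of 1 and 64, no filter, a filter at 100, the deposited scale, quantile normalization, no cross-hybridising probe sets, no trend, fits over the 2 groups compared, a replicate block, a 2-fold minimum, a rule without a test, and each array left out in turn. The split marked by the 5S ribosomal RNA control, a term for the 25th percentile of each array and scaling to the hybridisation controls were chosen after seeing the data.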

Results

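Gene expression was measured in fully expanded leaves of Arabidopsis thaliana on 10 Affymetrix arrays, each carrying 22810 probe sets. The title of the series asks how mutants of stress response pathways change expression while leaves senesce. Wild type leaves were taken at growth stage 3.9 and at stage 6.0. In the scale commonly used for this plant these stages mark the fully grown rosette and the opening of the first flower. Leaves of 3 altered genotypes were taken at stage 6.0. NahG plants carry a bacterial salicylate hydroxylase that degrades salicylic acid, ein2 is known as an ethylene-insensitive mutant and coi1 as a jasmonate-insensitive mutant. Each of the 5 groups had 2 arrays. Both wild type groups held 1 array of stock N933 (array 1) and 1 of stock N1644 (array 2). The labels of the stage 6.0 array of stock N1644 name the Col-0 line in another field, and the coi1 arrays carry the same stock code as the ein2 arrays, so these origins rest on conflicting labels. The title of that N1644 array, like its stock code, goes with the stage 3.9 array of stock N1644 and not with the N933 arrays. The probe sets of EIN2 and COI1 are unnamed here, so the mutated genes themselves were not checked.

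The arrays separated by stage first and by the NahG transgene second. The first principal component held 51.5% of the variance and set the 2 stage 3.9 arrays apart from all others. The second held 21% and set the 2 NahG arrays apart. Across probe sets, correlations within groups ran from 0.941 to 0.977, against 0.70 to 0.772 between stage 3.9 and stage 6.0 arrays. Between 9738 and 10835 probe sets per array reached a signal of 50. The 3' to 5' signal ratio of the actin control, a measure of RNA integrity, lay between 1.54 and 2.7. It was 2.43 and 2.7 at stage 3.9, 2.08 and 1.77 in wild type at stage 6.0, 2.6 and 2.11 in NahG, 2.06 and 1.95 in ein2, and 1.54 and 2.56 in coi1. That of the ubiquitin control differed between groups, at 2.12 and 2.24 on the stage 3.9 arrays, 1.34 and 1.3 on the stage 6.0 wild type arrays, 1.66 and 1.6 in NahG, 1.45 and 1.52 in ein2, and 1.38 and 1.54 in coi1. The GAPDH ratio was 0.974 and 0.958 at stage 3.9, 1.17 and 1.02 in wild type at stage 6.0 and 1.28 and 1.21 in NahG. After filtering, 12184 probe sets were tested, of which 6452 name exactly 1 gene.

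**Figure D1:**
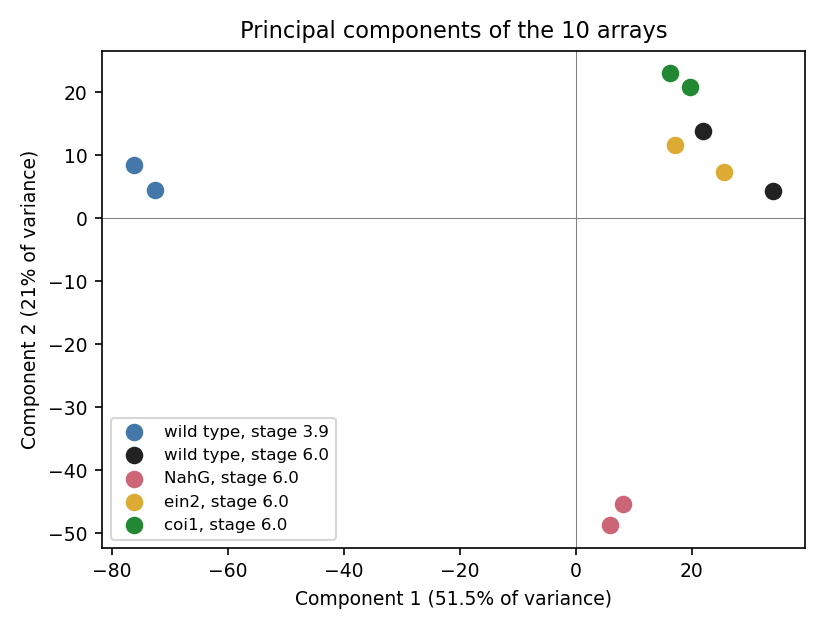
Scores of the 10 arrays on the first and second principal components of log2 signal over the tested probe sets, with each point an array and each colour a group of 2 arrays. The stage 3.9 arrays lie apart on component 1, which holds 51.5% of the variance, and the NahG arrays on component 2, which holds 21%.

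Between stage 3.9 and stage 6.0, transcripts of anthocyanin synthesis, senescence-associated genes, autophagy genes and vacuolar proteases rose as lists in wild type leaves, and those of photosynthesis fell. None of these 5 list shifts passed with an estimated correlation (adjusted p from 0.0832 to 0.319), and 7 of 11 autophagy genes passed singly. DFR, which encodes the dihydroflavonol reductase of anthocyanin synthesis, rose from a mean signal of 40.0 ± 13.5 to 1792 ± 314 (SD, n = 2 arrays per stage), a log2 change of 5.02 ± 0.21 (SE). PSAN, a photosystem I subunit, dropped from 4149 ± 944 to 440.3 ± 12.2 (SD, n = 2), a log2 change of -3.17 ± 0.20 (SE). SAG29, a sugar transporter that marks senescing leaves, rose from 12.3 ± 5.12 to 508.9 ± 485 (SD, n = 2), a log2 change of 3.82 ± 0.52 (SE), with 2.7 without stage 6.0 wild type array 1 and 4.95 without array 2. This size also depends on the 16 added before taking logs, and was 4.88 with 1 added and 2.59 with 64 added. In all, 2461 probe sets rose and 2099 fell at an adjusted p under 0.05 in limma, out of 12184.

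Of the 5 measured genes of phenylpropanoid, flavonoid and anthocyanin synthesis 4 rose, and 4 also when adjusted over the list alone. The anthocyanin glucosyltransferase gene UGT75C1 changed by 5.27 ± 0.28 (log2 ± SE), UF3GT by 4.35 ± 0.24 and the flavonoid 3-O-glucosyltransferase gene UGT78D2 by 3.18 ± 0.22. UGT78D1, a flavonol rhamnosyltransferase gene, stood at -0.43 ± 0.28 and did not pass. The median of the list was 4.35 (camera adjusted p = 0.000237; adjusted p = 0.0927 with an estimated correlation). Among senescence-associated genes 3 of 4 rose, 4 adjusted over the list alone, with a median of 2.14 (camera adjusted p = 0.00298; adjusted p = 0.0832 with an estimated correlation). These were SAG29, the transcription factor gene WRKY6 at 3.35 ± 0.19 and WRKY53 at 0.93 ± 0.23, while SAG101 measured 0.57 ± 0.22. Mean signals at stage 3.9 were only 1.97 for UGT75C1 and 2.67 for WRKY6, so the size of their changes was set largely by the 16 added before taking logs.

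Autophagy genes rose in 7 of 11 cases, 8 adjusted over the list alone, with a median of 0.96 (camera adjusted p = 0.00298; adjusted p = 0.319 with an estimated correlation). The ubiquitin-like ATG8 genes ATG8B, APG8A and ATG8H rose by 2.15 ± 0.28, 2.07 ± 0.29 and 2.03 ± 0.41 (log2 ± SE), and ATG3 by 1.05 ± 0.20. The change of ATG8H was 1.38 without stage 6.0 wild type array 1 and 2.68 without array 2. ATG8F measured -0.10 ± 0.22. Of the 6 vacuolar and cysteine protease genes 5 rose, 5 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 0.00115; adjusted p = 0.0832 with an estimated correlation). They included the vacuolar processing enzyme genes BETA-VPE at 1.91 ± 0.18, GAMMA-VPE at 1.65 ± 0.23 and ALPHA-VPE at 1.21 ± 0.31. The cathepsin B-like CATHB3 rose by 1.32 ± 0.18, whereas RD19C, at 0.42 ± 0.22, did not pass.

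Each of the 9 measured photosynthesis genes fell, 9 adjusted over the list alone, with a median of -1.64 (camera adjusted p = 3.77e-07; adjusted p = 0.0927 with an estimated correlation). The light-harvesting gene LHCB4.2 dropped to 271.2 ± 45.6 from 3482 ± 2030 (SD, n = 2), a log2 change of -3.48 ± 0.33 (SE), with -2.86 without stage 3.9 array 1 and -4.11 without array 2. The photosystem I gene PSAE-1 changed by -2.15 ± 0.21, and the Rubisco activase gene RCA by -0.91 ± 0.22. The list of ethylene synthesis and response did not shift (median -0.51, mean -0.40, camera adjusted p = 0.474). Within it EIN3, a transcription factor of ethylene signalling, rose by 0.66 ± 0.18 and RTE1 changed by -0.60 ± 0.17, 1 rise and 1 fall adjusted over the list alone. PDF1.2, the plant defensin gene, measured -1.22 ± 0.67 (adjusted p = 0.179).

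Lists with fewer than 3 measured genes were not tested as groups. The nitrate transporter gene NRT2.5 and PPDK, pyruvate orthophosphate dikinase, both of the nutrient remobilisation list, rose by 2.11 ± 0.23 and 1.66 ± 0.23 (log2 ± SE). The dehydration-responsive COR47 rose by 1.97 ± 0.27, the beta-oxidation gene AIM1 by 0.85 ± 0.19, GRX480 of the salicylic acid list by 1.7 ± 0.25, the methyltransferase gene BSMT1 of the jasmonate list by 1.26 ± 0.44 and the evening clock gene GI by 1.3 ± 0.37. The chlorophyll breakdown gene NOL at 0.30 ± 0.18, the response regulator RR16 at 0.30 ± 0.41 and the morning-listed COR27 at 1.55 ± 0.88 did not pass. The size of the BSMT1 change, from a mean signal of 6.5 at stage 3.9, depends on the added 16, with 2.32 with 1 added and 0.57 with 64 added, where it did not pass (adjusted p = 0.0625). GASA9, the only measured member of the guard cell marker list, changed by -3.0 ± 0.28.

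Outside the lists, rises among probe sets of 1 named gene included AT5G39520 (5.24 ± 0.26, log2 ± SE), AT1G05340 (4.79 ± 0.41), AT1G68620 (4.28 ± 0.38) and AT2G25625 (4.26 ± 0.29). AT3G61930 rose from 2.37 ± 0.928 to 985.2 ± 593 (SD, n = 2), a log2 change of 5.63 ± 0.41 (SE) with 16 added to the signal, 8.08 with 1 added and 3.86 with 64 added, so the size of this change is not fixed by the data. It was 4.99 without stage 6.0 wild type array 1 and 6.27 without array 2. Without stage 3.9 arrays 1 and 2, AT1G05340 measured 5.45 and 4.12 and AT1G68620 4.96 and 3.59. Falls included AT2G10940 (-5.35 ± 0.25), AT3G16370 (-5.23 ± 0.21), AT1G21500 (-4.83 ± 0.29), the expansin gene EXPA8 (-4.82 ± 0.30) and AT5G63180 (-4.81 ± 0.19). AT1G05340 at stage 3.9 (mean signal 15.5) and EXPA8 and AT5G63180 at stage 6.0 (8.45 and 14.3) also lay below the added 16, which shrinks such changes. AT1G29670, AT1G09750 and AT5G22580 had folds of 21, 20.2 and 18.5 downward after 16 was added to the signal. Their mean signals fell from 1440 to 48.7, from 755.7 to 21.03 and from 1286 to 54.89, so the folds of the signals themselves were larger.

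Bacterial and phage hybridisation controls were 1.75 times as bright on the stage 3.9 arrays as on the stage 6.0 wild type arrays. They also differed between arrays of a group, at 181 and 363 in coi1, 265 and 339 in ein2 and 295 and 228 in NahG. In wild type they stood at 438 and 409 at stage 3.9 and at 230 and 255 at stage 6.0. Scaling to them adds these differences to the spread of every gene, so its p-values are not comparable with those of the main fit. Scaling to these controls, chosen after seeing the data, moved the median log2 change of all genes from 0.05 to 0.72, gave 3807 rises and 444 falls and brought RTE1 to 0.07 and the ethylene list median to 0.19. The 5 list shifts described above kept their direction there, with medians of -0.84 for photosynthesis, 1.67 for autophagy and 1.99 for proteases. After quantile normalization the photosynthesis median was -0.97. Of 38 named calls, 5 were lost on leaving out single arrays. EIN3 was lost without stage 6.0 wild type array 2 (adjusted p = 0.0987), GI without stage 3.9 array 1 (0.66, adjusted p = 0.121) or stage 6.0 wild type array 2 (0.93, 0.124), and WRKY53 without stage 3.9 array 2 (0.59, 0.0674) or stage 6.0 wild type array 1 (0.83, 0.0595). Without stage 3.9 array 2 GI measured 1.94. RTE1 was lost without stage 3.9 array 1 (0.0845) or either stage 6.0 wild type array (0.0724, 0.0595). BSMT1 was lost without stage 3.9 array 1 (0.0689), stage 3.9 array 2 (0.14), stage 6.0 wild type array 1 (0.54, adjusted p = 0.35), either NahG array (0.0649, 0.0638) or either coi1 array (0.0606, 0.0607), and it measured 1.98 without stage 6.0 wild type array 2. Without stage 3.9 array 2, COR27 (3.52) and PDF1.2 (-2.63) passed, and COR27 also when scaled to the hybridisation controls (2.14). BSMT1 was also lost without a filter (0.094), with a filter at 100 (0.0511), after quantile normalization (0.0533) and with the 25th percentile term (0.0749). In a fit over the 2 groups BSMT1 (0.116), EIN3 (0.0564), RTE1 (0.0542) and GI (0.0736) were lost. With the 5S ribosomal RNA split BSMT1, WRKY53 and RTE1 were lost, with log2 changes of 0.541, 0.828 and -0.595. For the stage comparison this split amounts to leaving out stage 6.0 wild type array 1.

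**Figure D2:**
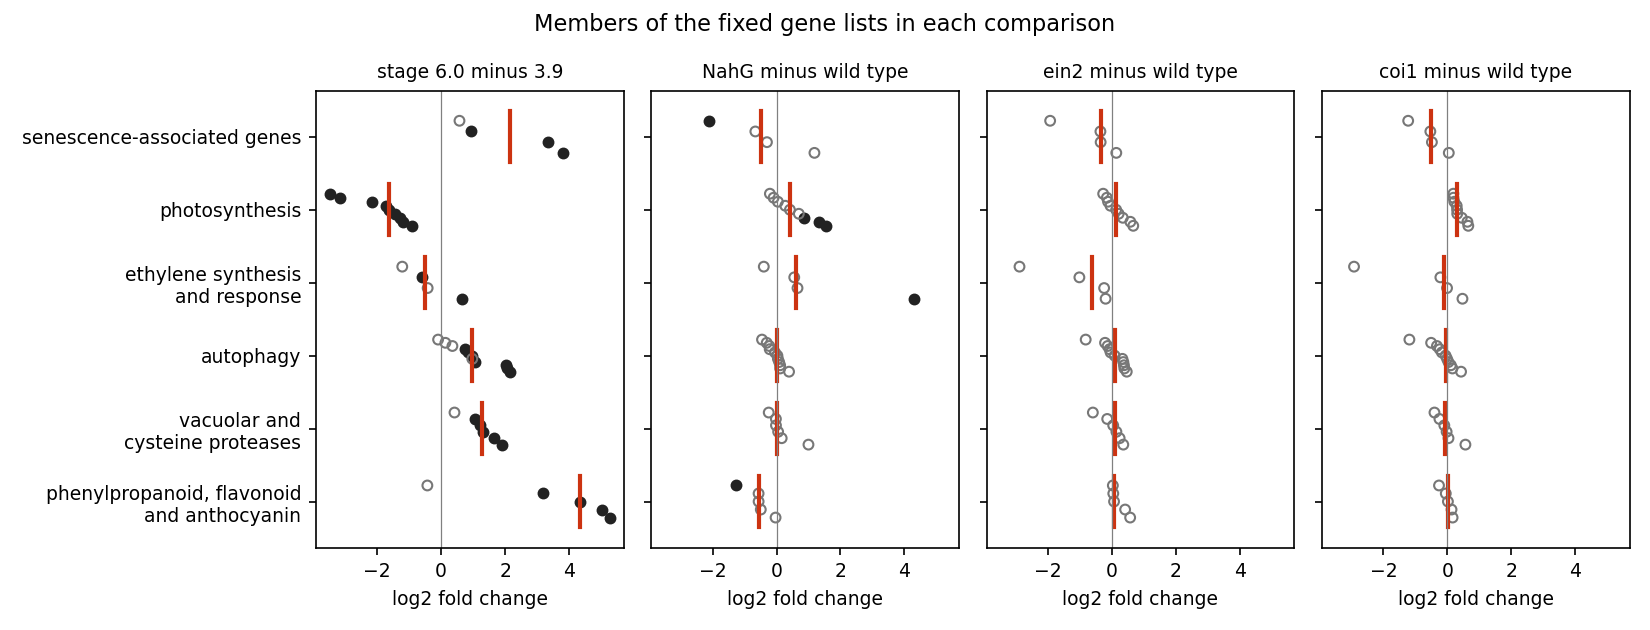
Log2 fold change of each measured member of 6 gene lists in 4 comparisons, stage 6.0 minus stage 3.9 in wild type and each genotype minus wild type at stage 6.0. Filled circles passed an adjusted p of 0.05 over all probe sets, open circles did not, and the red line is the list median. All 9 photosynthesis genes lie left of 0 in the stage panel.

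In NahG leaves at stage 6.0, plant defensin genes were far higher than in wild type and AT5G03350, a legume lectin-like gene, was near the bottom of the signal range. PDF1.2 rose from 197.3 ± 59.1 to 4134 ± 159 (SD, n = 2 per group), a log2 change of 4.31 ± 0.67 (SE), and PDF1.2b rose by 4.05 ± 0.58. AT5G03350 dropped from 1510 ± 181 to 1.21 ± 0.428 (SD, n = 2). Its log2 change was -6.46 ± 0.30 (SE) with 16 added to the signal, -9.43 with 1 added and -4.59 with 64 added, so its size depends on this constant and is no bound. The transcription factor gene WRKY53 dropped from a mean signal of 179.6 to 29.25. With 16 added to the signal this was a fold of 4.32, a log2 change of -2.11 ± 0.23 (SE). In total 440 probe sets rose and 670 fell at an adjusted p under 0.05 in limma. PDF1.2b was measured by a probe set marked as cross-hybridising, so its signal may include that of related defensins.

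The jasmonate list had 2 measured genes and both rose in NahG, the thionin gene THI2.1 by 2.22 ± 0.31 and BSMT1 by 2.16 ± 0.44 (log2 ± SE). GRX480, the only gene with a named probe set among the 30 of the salicylic acid list, fell by 1.97 ± 0.25. NRT2.5 changed by -1.34 ± 0.23. Photosynthesis genes rose in 3 of 9 cases, 4 adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.0253; adjusted p = 0.339 with an estimated correlation), and a median of 0.21 after quantile normalization, where the list did not pass (0.0736). They were PSAN at 1.56 ± 0.20, LHCB4.2 at 1.33 ± 0.33 and PSAE-1 at 0.85 ± 0.21. Genes of phenylpropanoid, flavonoid and anthocyanin synthesis had a median of -0.56 (camera adjusted p = 0.0405; adjusted p = 0.339 with an estimated correlation). Only UGT78D2, at -1.28 ± 0.22, fell, 1 also adjusted over the list alone, and DFR measured -0.49 ± 0.21.

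The remaining lists did not pass in NahG over all arrays. The ethylene list passed when scaled to the hybridisation controls (camera adjusted p = 0.000356) and the senescence-associated list without a filter (0.0403) and with fry (0.013). Among senescence-associated genes WRKY53 alone fell, 2 adjusted over the list alone (median -0.48, camera adjusted p = 0.0825), and SAG29 measured 1.19 ± 0.52. In the ethylene list PDF1.2 alone rose, 2 adjusted over the list alone (median 0.60, camera adjusted p = 0.0825). None of 11 autophagy genes (camera adjusted p = 0.818) and none of 6 protease genes (camera adjusted p = 0.714) passed, over all genes or adjusted over the list alone. The autophagy median of 0.03 and mean of -0.04 differ in sign, and its test pointed down. Scaled to the hybridisation controls the autophagy median was -0.07 and the protease median, 0.02 before, was -0.08, and after quantile normalization the autophagy median was -0.05. The median of all genes in NahG moved with that scaling to the controls too, from 0.01 to -0.07. ATG3 measured -0.45 ± 0.20 and ALPHA-VPE 1.0 ± 0.31. COR15A at 0.95 ± 0.38, GASA9 at 0.94 ± 0.28, GI at 0.46 ± 0.37, COR27 at 0.67 ± 0.88, RR16 at 0.32 ± 0.41, NOL at -0.06 ± 0.18, COR47 at -0.05 ± 0.27, SDP1 at 0.05 ± 0.24 and AIM1 at 0.03 ± 0.19 (log2 ± SE) did not pass.

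Other rises in NahG included AT2G41800 (4.21 ± 0.44, log2 ± SE), AT4G17470 (4.21 ± 0.32), AT2G19970 (4.19 ± 0.28), the pectate lyase-like gene AT3G27400 (4.02 ± 0.31), AT3G28220 (3.48 ± 0.48) and AT1G54020 (3.36 ± 0.25). Other falls included AT5G55450 (-4.56 ± 0.36), AT1G19960 (-4.47 ± 0.26), the calmodulin-like gene AT2G41090 (-4.35 ± 0.32), AT5G52760 (-3.99 ± 0.35), AT1G10340 (-3.92 ± 0.33), AT4G29480 (-3.73 ± 0.18) and AT3G60420 (-3.51 ± 0.24). AT2G41090 measured -3.74 without NahG array 1 and -4.96 without array 2. Mean signals lay below the added 16 in wild type for AT2G41800 (6.84), AT4G17470 (8.2), AT2G19970 (0.956) and AT1G54020 (10.8), and in NahG for AT5G55450 (2.06), AT1G19960 (13.9), AT5G52760 (13.3), AT1G10340 (15.1) and AT4G29480 (14.4), so the sizes of these changes depend on that constant too.

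Without stage 6.0 wild type array 2 the NahG count of 1110 became 615, without NahG array 1 it became 455 and without NahG array 2 it became 698. LHCB4.2 and PSAE-1 did not pass without any of the 4 arrays compared, with adjusted p from 0.0712 to 0.161. BSMT1 did not pass without stage 6.0 wild type array 2 (1.44, adjusted p = 0.0652) or NahG array 1 (1.96, 0.118), and measured 2.87 without stage 6.0 wild type array 1. The photosynthesis shift was lost without stage 6.0 wild type array 1 (camera adjusted p = 0.128) or NahG array 1 (0.0599) and with fry (0.0573), and the anthocyanin shift without wild type array 2 (0.133) or NahG array 1 (0.0627), with 1 added (0.0642), with a filter at 100 (0.103), with fry (0.0663) and when scaled to the hybridisation controls (0.0766). Leaving out stage 3.9 array 1 or 2 brought the ethylene list past the threshold (camera adjusted p = 0.0215 and 0.0218) and COR15A too (0.0204 and 0.0202), and leaving out stage 6.0 wild type array 2 brought GASA9 past it (0.0126). Scaling to the hybridisation controls gave 424 calls and ended those of LHCB4.2, PSAE-1 and UGT78D2 (adjusted p from 0.0616 to 0.34). Their log2 changes there were 1.24, 0.752 and -1.39. LHCB4.2 (0.0775) and PSAE-1 (0.101) were also lost without a filter and BSMT1 with 1 added (0.0575). ALPHA-VPE passed with 64 added (0.0232), without trend (0.0431) and in a fit over the 2 groups (0.0406), where COR15A passed too (0.0427), and GASA9 passed after quantile normalization (0.0337) and with the 25th percentile term (0.0392).

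**Figure D3:**
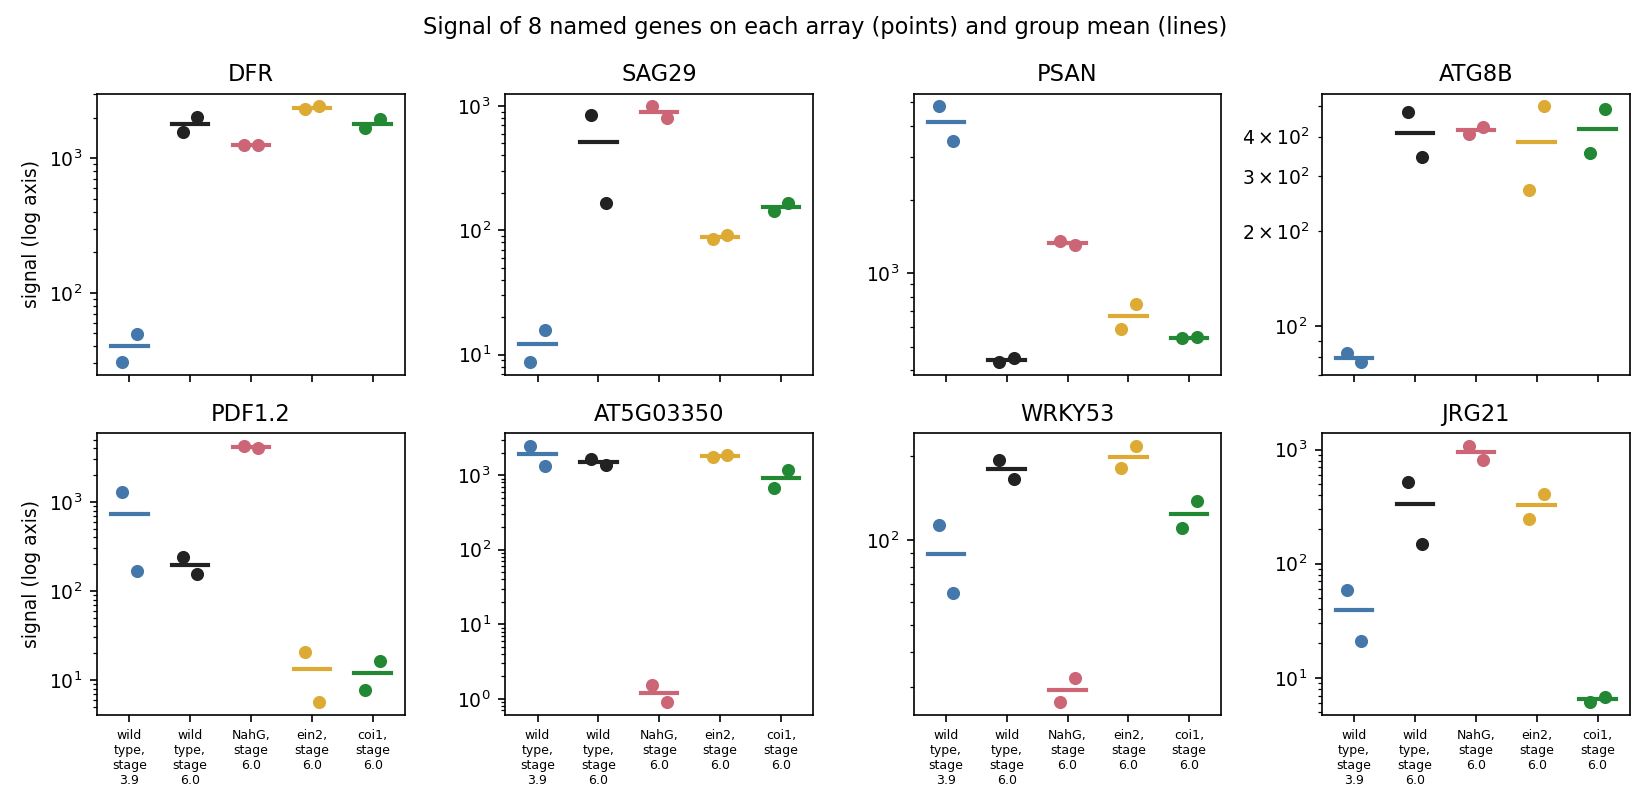
Signal of 8 genes on each array, on a log axis, with points for arrays and a line for the mean of each group of 2. PDF1.2 has its highest mean in NahG, at 4134, AT5G03350 its lowest there, at 1.21, and JRG21 its lowest in coi1, at 6.49.

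The ein2 mutant differed from wild type at few probe sets, with 6 rises and 9 falls at an adjusted p under 0.05 in limma and 1227 probe sets at an unadjusted p under 0.05. The 4 called genes with a name all rose. They were DI21, known as a drought-induced gene, from 57.1 ± 9.18 to 191.4 ± 3.14 (SD, n = 2 per group), AT5G62130 by 1.48 ± 0.17 (log2 ± SE), AT1G75900 by 1.44 ± 0.20 and ZW9 by 1.26 ± 0.17. The genes nearest to the threshold on the lower side were AT4G16260, a glucanase-like gene, at -2.37 ± 0.41 (adjusted p = 0.0624), the polygalacturonase gene ADPG1 at -1.82 ± 0.32 (0.0714) and AT2G41380 at -0.87 ± 0.17 (0.095). On the higher side they were AT4G30660 at 1.1 ± 0.18 (0.0533), AT1G09310 at 1.46 ± 0.25 (0.0632) and AT1G66890 at 0.93 ± 0.17 (0.0942).

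The ethylene synthesis and response list was lower in ein2, with a median of -0.63 (camera adjusted p = 0.00375; adjusted p = 0.221 with an estimated correlation and 0.0995 with fry). None of its 4 genes passed over all genes and 2 fell adjusted over the list alone. PDF1.2 had a mean signal of 13.2 ± 10.7 against 197.3 ± 59.1 in wild type (SD, n = 2), a log2 difference of -2.89 ± 0.67 (SE, adjusted p = 0.142). ARL measured -1.02 ± 0.28, EIN3 -0.20 ± 0.18 and RTE1 -0.24 ± 0.17. No member of the other lists passed over all genes. The senescence-associated list had a median of -0.36 (camera adjusted p = 0.0786), with 1 fall adjusted over the list alone and SAG29 at -1.93 ± 0.52 (adjusted p = 0.209). Photosynthesis (median 0.13, camera adjusted p = 0.358), autophagy (0.09, 0.358), proteases (0.09, 0.654) and anthocyanin genes (0.07, 0.214) did not pass over all arrays, with 0 members adjusted over the list alone in each. All 4 of these medians turned negative when the arrays were scaled to the hybridisation controls, at -0.17, -0.19, -0.22 and -0.18, and the protease median after quantile normalization, at -0.10. Scaling to these controls also moved the median of all genes in ein2 from 0.01 to -0.26, and the 4 list medians stayed above it.

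Of the shorter lists, RR16, a response regulator, stood at -1.73 ± 0.41 (log2 ± SE, adjusted p = 0.155) in ein2. BSMT1 at -0.75 ± 0.44, GRX480 at 0.44 ± 0.25, COR15A at 0.57 ± 0.38, UF3GT at 0.57 ± 0.24, ATG8H at -0.82 ± 0.41 and LHCB4.2 at 0.67 ± 0.33 were also not past the threshold. Leaving out ein2 array 1 left 0 calls in limma and leaving out ein2 array 2 left 3. The count was 76 without either stage 3.9 array, 40 without stage 6.0 wild type array 2, 6 without NahG array 1, NahG array 2 or coi1 array 2, and 5 without coi1 array 1. AT5G62130 was lost without either ein2 array (adjusted p = 0.134 and 0.11). DI21, AT1G75900 and ZW9 were lost without stage 6.0 wild type array 1 (0.117 to 0.167), either NahG array (0.0701 to 0.108), either ein2 array (up to 0.306) or either coi1 array (0.0717 to 0.106), and DI21 also without stage 6.0 wild type array 2 (0.0568). Scaling to the hybridisation controls moved the median log2 change of all genes from 0.01 to -0.26, gave 3 rises and 44 falls and ended the 4 named calls (adjusted p from 0.35 to 0.841). Quantile normalization gave 9 rises and 8 falls. DI21 was also lost with 1 added (0.151), with a filter at 100 (0.0503), without trend (0.054) and with the 25th percentile term (0.053), and DI21, AT1G75900 and ZW9 were lost without a filter (0.11 to 0.131) and in a fit over the 2 groups (0.0597 to 0.116).

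Other ein2 results passed in some settings. Without either stage 3.9 array PDF1.2 (adjusted p = 0.0013 and 0.00128), AT4G16260 (0.0013 and 0.00128), ADPG1 (0.0293 and 0.0303), ARL (0.0354 and 0.034), AT4G30660 (0.0287 and 0.0281), AT1G09310 (0.0332 and 0.0322), AT1G66890 (0.0456 and 0.0453) and AT2G41380 (0.0476 and 0.0469) passed. Without stage 6.0 wild type array 2, SAG29, RR16, ADPG1, the senescence-associated list and the anthocyanin list passed. Stage 6.0 wild type arrays 1 and 2 had signals of 851.6 and 166.1 for SAG29, 341.5 and 125.6 for RR16 and 118.4 and 57.36 for ADPG1. The autophagy list passed without stage 6.0 wild type array 1 or ein2 array 1. It passed with the 5S ribosomal RNA split too, which is no separate setting here, since it also compares ein2 with wild type array 2 alone. Scaled to the hybridisation controls PDF1.2 (5.47e-08), AT4G16260 (7.93e-06), ADPG1 (0.000522), SAG29 (0.000797), RR16 (0.00459) and the senescence-associated list (0.00126) passed, and that list also without a filter (0.033). These controls differed between the arrays of a group, so p-values from this scaling are not comparable with those of the main fit. PDF1.2 (0.0486) and AT4G16260 (0.0486) passed in a fit over the 2 groups, AT4G16260 with 64 added (0.0431) and AT4G30660 after quantile normalization (0.0287) and with the 25th percentile term (0.024). The sizes for PDF1.2 and ADPG1, with mean signals of 13.2 and 12.3 in ein2, depend on the added 16.

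In coi1 leaves the genes lower than in wild type included JRG21, a jasmonate-regulated oxygenase gene, and its relative AT5G05600. JRG21 had a mean signal of 6.49 ± 0.506 against 335.0 ± 264 in wild type (SD, n = 2 per group), a log2 change of -3.72 ± 0.48 (SE), and AT5G05600 fell by 3.51 ± 0.31. The wild type arrays differed for JRG21, so its change was -2.87 without stage 6.0 wild type array 1 and -4.58 without array 2. It did not pass without coi1 array 1 (adjusted p = 0.0872) or 2 (0.0857). With mean signals of 6.49 and 8.45 in coi1, the sizes for JRG21 and AT5G05600 also depend on the added 16. The jacalin-like lectin gene AT1G52000 changed by -2.01 ± 0.21 and the berberine bridge enzyme-like gene AT2G34810 by -1.94 ± 0.20 (SE, n = 2). In total 47 probe sets rose and 76 fell at an adjusted p under 0.05 in limma.

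Further falls in coi1 were AT2G39420 (-1.93 ± 0.23, log2 ± SE), the osmotin-like gene OSM34 (-1.92 ± 0.30), AT1G30700 (-1.80 ± 0.32) and AT4G29700 (-1.78 ± 0.27). GRX480 of the salicylic acid list fell by 1.62 ± 0.25. The rises were AT3G49400 (2.2 ± 0.32), AT3G16370 (1.64 ± 0.21), the light-harvesting gene LHCB4.3 (1.41 ± 0.27), AT5G59250 (1.33 ± 0.23), AT1G20070 (1.28 ± 0.20), AT3G48420 (1.18 ± 0.19), AT5G13410 (1.14 ± 0.22) and AT5G11930 (1.12 ± 0.20). Mean signals below the added 16, at 4.23 in coi1 for AT4G29700 and at 13.3 and 9.21 in wild type for AT3G49400 and AT5G59250, leave the sizes of these 3 changes dependent on it. PDF1.2 was close to its level in ein2, 12.0 ± 6.06 against 197.3 ± 59.1 in wild type (SD, n = 2), a log2 difference of -2.92 ± 0.67 (SE, adjusted p = 0.0678), of which the size depends on the added 16 too.

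Photosynthesis genes were higher in coi1 as a list, with a median of 0.31 (camera adjusted p = 0.0133; adjusted p = 0.601 with an estimated correlation and 0.19 with fry). None of the 9 passed over all genes and 2 rose adjusted over the list alone. PRK, phosphoribulokinase, measured 0.66 ± 0.19 and SBPASE, sedoheptulose bisphosphatase, 0.63 ± 0.19 (log2 ± SE). The senescence-associated list had a median of -0.50 (camera adjusted p = 0.0642), with SAG29 at -1.22 ± 0.52 and SAG101 at -0.53 ± 0.22. Ethylene (median -0.11, camera adjusted p = 0.649), autophagy (-0.05, 0.575), protease (-0.06, 0.827) and anthocyanin genes (0.02, 0.827) did not pass over all arrays. Scaled to the hybridisation controls the ethylene list (0.00994) and the senescence-associated list (0.0159) passed. Adjusted over the list alone, 1 ethylene gene rose and 1 fell, and 0 passed in the senescence, autophagy, protease and anthocyanin lists. The anthocyanin median and mean were just above 0 while the direction of its test was down, and the median was -0.04 after quantile normalization and -0.06 when scaled to the hybridisation controls. That scaling to the controls moved the median of all genes in coi1 from 0.04 to -0.02. ATG8H measured -1.18 ± 0.41, BETA-VPE 0.57 ± 0.18, BSMT1 -1.15 ± 0.44 and COR15A -0.71 ± 0.38.

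The 5S ribosomal RNA control was nearly absent from both coi1 arrays (signals of 2.1 and 2.2) and stage 6.0 wild type array 1 (3.6), against 193.3 to 594.8 on the other 7 arrays. A fit with this split as a covariate, chosen after seeing the data, compares coi1 with wild type array 1 alone, and NahG and ein2 with wild type array 2 alone. It gave 119 calls in coi1, 66 of them shared with the 123, and 6 named calls ended (adjusted p from 0.0556 to 0.139). Their log2 changes went from 1.28 to 1.12 for AT1G20070, 1.14 to 1.05 for AT5G13410, 1.33 to 1.42 for AT5G59250, -1.62 to -1.43 for GRX480, 1.41 to 1.54 for LHCB4.3 and -1.92 to -1.79 for OSM34. With it the senescence-associated list (camera adjusted p = 0.007) and the autophagy list (0.0141) were lower in coi1. It gave 747 calls in NahG, where LHCB4.2, PSAE-1 and the photosynthesis list did not pass (adjusted p = 0.136, 0.139 and 0.128), with LHCB4.2 at 1.17 after 1.33 and PSAE-1 at 0.77 after 0.85. It gave 12 calls in ein2, where DI21, AT1G75900 and ZW9 did not pass (0.117 to 0.166), with log2 changes of 1.38 after 1.51, 1.34 after 1.44 and 1.13 after 1.26.

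Leaving out coi1 array 1 left 13 calls and leaving out coi1 array 2 left 14. Of the 17 named genes called in coi1, 14 were lost without array 1 (adjusted p from 0.0561 to 0.272) and 14 without array 2 (0.0569 to 0.282). AT5G05600, AT1G52000 and AT2G34810 passed whichever array was left out. The count was 73 without NahG array 1, 73 without NahG array 2, and 308 and 306 without stage 3.9 arrays 1 and 2. Without stage 6.0 wild type array 1 or 2, 7 and 6 of the 17 were lost (up to 0.181 and 0.139), and without single NahG or ein2 arrays 2 each (up to 0.0786 and 0.0707). The photosynthesis shift was lost without stage 6.0 wild type array 1 (camera adjusted p = 0.306) or coi1 array 2 (0.178). PDF1.2 passed without stage 3.9 array 1 (adjusted p = 0.000779) or 2 (0.00076), in a fit over the 2 groups (0.00978) and when scaled to the hybridisation controls (1.08e-08). The last value is not comparable with the others, since these controls stood at 181 and 363 on the 2 coi1 arrays. Without stage 6.0 wild type array 2, SAG29, the senescence-associated list and the autophagy list passed. The senescence-associated list also passed without stage 3.9 array 2 (camera adjusted p = 0.0486). SAG29 had signals of 851.6 and 166.1 on stage 6.0 wild type arrays 1 and 2, and 143.3 and 166.4 in coi1. Its signal in coi1 thus lay far below array 1 and near array 2. Scaling to the hybridisation controls gave 8 rises and 100 falls and ended 7 of the named calls, all of them rises (0.052 to 0.635). Without a filter 9 were lost, LHCB4.3 (0.0928), AT5G59250 (0.0761), AT1G20070 (0.0557), AT5G13410 (0.0898), AT5G11930 (0.0698), OSM34 (0.0613), AT1G30700 (0.0859), AT4G29700 (0.0506) and GRX480 (0.0596). With 1 added OSM34 (0.237) and AT1G30700 (0.0969) were lost, AT5G59250 with 64 added (0.0644) and in a fit over the 2 groups (0.0534), and AT5G13410 after quantile normalization (0.0516). With the 5S ribosomal RNA split, which also compares coi1 with stage 6.0 wild type array 1 alone, SAG29 passed too. ATG8H passed with the 25th percentile term (adjusted p = 0.00562).

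The genotypes were also compared with each other, which tests whether their differences from wild type differ. NahG exceeded ein2 at PDF1.2 by 7.20 ± 0.67 (log2 ± SE, n = 2 per group), at PDF1.2b by 6.43 ± 0.58 and at AT4G16260 by 4.75 ± 0.41. It was lower at AT5G03350 by a log2 difference of -6.72 ± 0.30, at AT2G44240 of -5.66 ± 0.48 and at AT1G19960 of -4.84 ± 0.26. Against coi1, NahG was higher at PDF1.2 by 7.23 ± 0.67, at PDF1.2b by 6.34 ± 0.58 and at JRG21 by 5.4 ± 0.48, and AT5G03350, AT1G19960 and AT2G41090 stood at -5.72 ± 0.30, -4.81 ± 0.26 and -4.30 ± 0.32. These 12 differences passed whichever array was left out. The sizes for AT5G03350, AT2G44240 and AT1G19960, with mean signals of 1.21, 3.27 and 13.9 in NahG, depend on the added 16, as do those for PDF1.2 in ein2 and coi1 (13.2 and 12.0) and JRG21 in coi1 (6.49). Without NahG arrays 1 and 2, AT2G41090 stood at -3.69 and -4.91 against coi1. NahG was higher at 407 and lower at 510 probe sets than ein2, and higher at 613 and lower at 730 than coi1.

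The ethylene list was higher in NahG than in ein2, with 3 of 4 genes higher, 3 adjusted over the list alone, and a median of 1.24 (camera adjusted p = 0.00144; adjusted p = 0.249 with an estimated correlation). Besides PDF1.2, ARL differed by 1.67 ± 0.28 and RTE1 by 0.80 ± 0.17 (log2 ± SE). Anthocyanin genes were lower, with 2 of 5 past the threshold, 3 adjusted over the list alone, and a median of -0.61 (camera adjusted p = 0.00144; adjusted p = 0.249 with an estimated correlation). These were UGT78D2 at -1.35 ± 0.22 and DFR at -0.91 ± 0.21. Photosynthesis genes were higher, with PSAN alone past the threshold, 1 adjusted over the list alone, and a median of 0.32 (camera adjusted p = 0.013; adjusted p = 0.493 with an estimated correlation and 0.0967 with fry). The senescence-associated list had a median of -0.13 and a mean of 0.15, with SAG29 higher by 3.12 ± 0.52 and WRKY53 lower at -2.25 ± 0.23. Against coi1 its median was -0.24 and its mean 0.07. The protease list had a median of -0.04 and a mean of 0.15 against ein2. Against coi1 no list passed over all arrays, and the lowest camera adjusted p was 0.118, for anthocyanin genes. That list passed against coi1 without stage 3.9 array 1 or 2 (0.0467 and 0.0472), as did the ethylene list (0.0467 and 0.0472), and the autophagy list passed against ein2 without ein2 array 1 (0.0126). Against coi1 the ethylene list passed when scaled to the hybridisation controls (1.52e-07), the anthocyanin and autophagy lists with the 5S ribosomal RNA split (0.0165 each) and the anthocyanin list without a filter (0.0152).

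Between ein2 and coi1, ein2 was higher at JRG21 by 3.89 ± 0.48 (log2 ± SE), at AT5G05600 by 3.53 ± 0.31, at AT2G43530 by 2.79 ± 0.22 and at GRX480 by 2.06 ± 0.25. It was lower at AT3G49400 (-2.22 ± 0.32), AT5G22460 (-1.85 ± 0.24) and LHCB4.3 (-1.41 ± 0.27). The sizes for JRG21 and AT5G05600, at 6.49 and 8.45 in coi1, and AT3G49400, at 11.7 in ein2, depend on the added 16. In total it was higher at 42 and lower at 44 probe sets, and no list passed over all arrays (lowest camera adjusted p = 0.157). The photosynthesis list passed without coi1 array 1 (0.0103) and the autophagy list without ein2 array 1 (0.002). The autophagy list also passed with the 5S ribosomal RNA split (0.000488) and the 25th percentile term (0.00283), and the ethylene list without a filter (0.0435). With the 5S ribosomal RNA split as a covariate the count was 9, and AT3G49400, AT5G22460 and LHCB4.3, at -1.35, -1.55 and -1.67, did not pass (adjusted p from 0.237 to 0.311). With 1 added AT3G49400 (0.052) and LHCB4.3 (0.0516) were lost, and LHCB4.3 also without a filter (0.112), without trend (0.0531) and when scaled to the hybridisation controls (0.053).

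Single arrays moved these counts. Between NahG and ein2 the count of 917 became 419 without NahG array 1, 531 without ein2 array 1 and 418 without ein2 array 2. Between NahG and coi1 the 1343 became 645 and 719 without NahG arrays 1 and 2, and 592 and 619 without coi1 arrays 1 and 2, and it was 464 with the 5S ribosomal RNA split. Between ein2 and coi1 the 86 became 267 and 268 without stage 3.9 arrays 1 and 2, 132 and 131 without stage 6.0 wild type arrays 1 and 2, 55 and 56 without NahG arrays 1 and 2, 23 and 20 without ein2 arrays 1 and 2, and 11 and 15 without coi1 arrays 1 and 2. JRG21 did not pass there without ein2 array 2 or either coi1 array (adjusted p up to 0.0766). AT3G49400 was lost without any single ein2 or coi1 array (up to 0.194), AT5G22460 without ein2 array 1 or either coi1 array (up to 0.105) and LHCB4.3 without any single NahG, ein2 or coi1 array (up to 0.312). Scaling to the hybridisation controls gave 235 higher and 174 lower between NahG and ein2, and 549 calls between NahG and coi1.

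Genes that changed with stage in wild type were followed in each genotype. Of 1224 probe sets that rose at least 2-fold with stage, 243 were lower in NahG than in wild type of stage 6.0 and 24 were higher, with a median log2 difference of -0.34. Of 1172 that fell at least 2-fold, 199 were higher in NahG and 4 lower, with a median of 0.36. NRT2.5, GRX480 and UGT78D2 were among named genes that rose with stage and were lower in NahG, and PSAN, LHCB4.2 and PSAE-1 among those that fell with stage and were higher in NahG. In coi1 44 of the raised set were lower and 7 higher, and 24 of the lowered set were higher and 5 lower, with medians of -0.23 and 0.30. In ein2 6 of the raised set were lower and 2 higher, and 3 of the lowered set were higher and 0 lower. The ein2 medians were -0.21 and 0.14, and the second was -0.04 when scaled to the hybridisation controls. In NahG the 243 became 125 without NahG array 1, and the 199 became 113 without stage 6.0 wild type array 1, and 69 and 105 without NahG arrays 1 and 2. In coi1 the 44 became 99 and 84 without stage 3.9 arrays 1 and 2, 73 without stage 6.0 wild type array 2, 29 without either NahG array, and 5 and 7 without coi1 arrays 1 and 2. The 24 became 74 and 57 without stage 3.9 arrays 1 and 2, 5 and 12 without stage 6.0 wild type arrays 1 and 2, 6 without either NahG array, 10 and 7 without ein2 arrays 1 and 2, and 1 without either coi1 array. In ein2 the 6 became 25 and 20 without stage 3.9 arrays 1 and 2, 23 without stage 6.0 wild type array 2, and 0 to 3 without any single NahG, ein2 or coi1 array. The 3 became 15 and 14 without stage 3.9 arrays 1 and 2, 1 and 7 without stage 6.0 wild type arrays 1 and 2, and 0 in limma without any single NahG, ein2 or coi1 array.

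The stage 6.0 wild type arrays entered both sides of these contrasts, which alone gives an opposite sign. The covariance of stage change and NahG effect over all tested probe sets was -0.227, against -0.0296 in simulations without effects, and the correlations were -0.407 and -0.50. For ein2 the covariance was -0.104 and for coi1 -0.136, against the same -0.0296. With the stage change of 1 stock set against the genotype's difference from the array of the other stock, so that no array was shared, the covariance was -0.129 and -0.245 for NahG, -0.0195 and -0.109 for ein2, and -0.0403 and -0.153 for coi1. The medians in NahG were then -0.12 and 0.21 when the stage change came from stock N933, and -0.38 and 0.38 when it came from stock N1644. In ein2 they were -0.05 and 0.01 with stock N933 and -0.22 and 0.16 with stock N1644, and in coi1 -0.08 and 0.12, and -0.25 and 0.34.

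The calls of the genotypes overlapped in part. NahG and coi1 shared 10 rises where 1.7 would be shared by independent lists, and 12 falls against 4.18. In opposite directions, 23 probe sets were higher in NahG and lower in coi1 against 2.74, and 1 was lower in NahG and higher in coi1 against 2.58. NahG and ein2 shared 3 rises against 0.217 and 1 fall against 0.495, and ein2 and coi1 shared 0 rises against 0.0231 and 5 falls against 0.0561. The covariance of fold changes was 0.0602 for NahG and ein2, 0.0409 for NahG and coi1 and 0.0525 for ein2 and coi1. In simulations with shared wild type arrays and no effects it was 0.0296, 0.0295 and 0.0295. The correlations were 0.302, 0.172 and 0.386, against 0.501, 0.499 and 0.499 simulated, which are the values for equal spread in all groups. The stage 6.0 wild type arrays correlated at 0.952, against 0.966 in NahG and in ein2 and 0.977 in coi1. The simulated covariance may therefore be too low for these arrays. The simulated covariances show that sharing wild type arrays moves 2 genotypes in the same direction, so it may add to the calls shared in the same direction and not to the 23 in opposite directions. The 22 shared calls of NahG and coi1 in the same direction became 72 and 71 without stage 3.9 arrays 1 and 2, 9 and 12 without NahG arrays 1 and 2, 14 and 13 without ein2 arrays 1 and 2, and 2 and 3 without coi1 arrays 1 and 2. The 4 of NahG and ein2 became 31 without either stage 3.9 array, 13 without stage 6.0 wild type array 2, and 0 or 1 without any single NahG, ein2 or coi1 array. The 5 of ein2 and coi1 became 41 without either stage 3.9 array, 23 without stage 6.0 wild type array 2, and 0 to 2 without any single NahG, ein2 or coi1 array.

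The wild type stocks differed at 4 probe sets over both stages, 3 higher and 1 lower in N1644, with 1191 at an unadjusted p under 0.05. AT3G05220 was higher in stock N1644 by 1.54 ± 0.19 (log2 ± SE) and the nitrate transporter family gene AT3G21670 stood at -1.49 ± 0.20. Neither passed without any single NahG, ein2 or coi1 array (adjusted p from 0.055 to 0.111), nor did AT3G21670 without stage 3.9 array 1 (0.103) or 2 (0.104). Both were lost without a filter (0.104 and 0.151), in a fit over the 2 groups (0.293 each) and when scaled to the hybridisation controls (0.629 and 0.649), and AT3G21670 also after quantile normalization (0.0625) and with the replicate block (0.0546). The limma count was 0 without any single NahG, ein2 or coi1 array. It was 6, all higher, when scaled to the hybridisation controls and 3, all higher, after quantile normalization. Without a wild type array of 1 stage, the stock term rests on the single pair of arrays of the other stage. With the 5S ribosomal RNA split it rests on the stage 3.9 pair alone. Counts from those fits describe 1 pair of arrays and are not shown to be differences between stocks.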

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

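The test of shared arrays in NahG was chosen before the result was seen, and the tests of the common fraction in NahG, of the split in coi1 and of the stage 3.9 arrays in the stock pattern after it.

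Genes raised with stage were lower in NahG (median -0.34) and genes lowered with stage were higher (0.36), which the shared stage 6.0 wild type arrays alone might produce. With no array shared, the mean covariance was -0.187, below 0 for either stock, which argues against shared arrays as the whole cause. NahG leaves being less advanced by the same fraction for every gene is argued against as the whole cause. Of 2396 stage-changed probe sets 435 departed from that fraction, where 120 was the bound. Genes that NahG changed in other ways would depart too, and 1110 of 12184 tested probe sets were called in NahG. The test therefore cannot exclude a common delay beside other changes. A partial delay, or salicylic acid acting on some of these genes, stays open as a hypothesis, since the design names the transgene and neither was tested.

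The 5S ribosomal RNA control was nearly absent from 3 arrays, a signal outside the genes compared: both coi1 arrays and stage 6.0 wild type array 1. A sample preparation split marked by this control could have contributed to the 123 calls in coi1, and it cannot be told apart from the genotype, since a single wild type array lies on the side of the coi1 arrays. Against that array alone, assumed to vary like the other groups, 119 probe sets passed, 66 of them among the 123. For the 57 calls that ended, the median size was 1.17 before and 1.12 after, while the median standard error rose from 0.208 to 0.261. The coi1 mutation is the explanation the design names, and the stock code shared with ein2 leaves the origin of the plants open.

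The stage difference between single arrays was not the same in the wild type stocks at 52 probe sets. With its sign, the stage change was higher in N1644 than in N933 at 28 of them and lower at 24. These counts do not say in which stock the change was larger in size. At 38 of the 52 the change had opposite signs in the 2 stocks. Each stock has 1 array per stage, so all spread in this fit came from the other genotypes, and differences between single samples are not shown to be differences between stocks. The 5S split, or brightness at the low end (25th percentiles of 9.6 and 17.3 at stage 6.0, 15.5 and 15.1 at stage 3.9), might have set the stage 6.0 arrays apart. Yet 45 of the 52 had the larger difference between the stage 3.9 arrays (86.5%, exact 95% interval 74.2 to 94.4%). That interval treats the probe sets as independent, though all came from the same single arrays, so it measures no spread between samples. COR27 changed by 3.56 in N933 and -0.46 in N1644, SAG29 by 5.14 and 2.51 and RR16 by 1.52 and -0.93. The conflicting label of stage 6.0 array 2 stays open, as do a difference between the lines and between the samplings at stage 3.9, and no biological explanation was tested.

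The hybridisation controls, which no comparison used, were 1.75 times as bright at stage 3.9 as in stage 6.0 wild type, at 423.3 against 242.4. NahG and ein2 differed in their effects over the photosynthesis list (camera adjusted p = 0.013, median 0.32), the ethylene list (0.00144, median 1.24) and the anthocyanin list (0.00144, median -0.61) in the test of the pair, with adjusted p of 0.493, 0.249 and 0.249 with an estimated correlation.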

How the results depend on the processing

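The settings based on the 5S ribosomal RNA split, the 25th percentile and the hybridisation controls were chosen after the results were seen. With 2 arrays per group, every count depended on single arrays, and where 1 array of a group was left out the lone array was assumed to vary like the other groups. Leaving out an array of a group outside a comparison left its log2 changes as they were, as for PDF1.2 in ein2 at -2.89 without a stage 3.9 array. There the shared estimate of spread moved, and not the difference. The cause of the other dependences was not tested.

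Leaving out each array in turn, the counts ran from 3202 to 4420 for stage, 455 to 1359 for NahG, 0 to 76 for ein2, 13 to 308 for coi1, 418 to 1108 for NahG against ein2, 592 to 1703 for NahG against coi1, 11 to 268 for ein2 against coi1 and 0 to 301 for stock. List shifts numbered 10 to 16 against 12. Stage-raised genes lower in NahG numbered 125 to 331 (median -0.422 to -0.287) and stage-lowered genes higher 69 to 253 (0.337 to 0.481). For ein2 these were 0 to 25 (-0.293 to -0.168) and 0 to 15 (0.085 to 0.254), and for coi1 5 to 99 (-0.343 to -0.182) and 1 to 74 (0.25 to 0.403). Shared calls ran from 0 to 31 for NahG and ein2, 2 to 72 for NahG and coi1 and 0 to 41 for ein2 and coi1. Named calls held in every case for 33 of 38 genes in stage, 22 of 25 in NahG, 0 of 4 in ein2 and 3 of 17 in coi1.

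The replicate block pairs mutant arrays that share only a number (correlation of deviations 0.337 for NahG and ein2, -0.133 for NahG and coi1, 0.216 for ein2 and coi1). Wild type arrays were paired by stock and not with the mutant arrays, whose deviations ran against those at stage 6.0 (-0.302 for NahG, -0.475 for ein2, -0.193 for coi1). With the block the counts were 52 for ein2, 225 for coi1 and 197 for ein2 against coi1. The senescence-associated list passed in coi1 (0.0437), PDF1.2 in ein2 (0.0382) and coi1 (0.0117), and AT4G16260 (0.0385) and AT4G30660 (0.0444) in ein2. Stage-raised genes lower and stage-lowered genes higher then numbered 18 and 10 in ein2 and 86 and 44 in coi1.

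Requiring a 2-fold change as well gave 2396 for stage, 670 for NahG and 774 for NahG against coi1. A 2-fold change in every pair of arrays, without a test, gave 1505 for stage, 437 for NahG, 48 for ein2, 442 for NahG against ein2 and 573 for NahG against coi1. Fits over the 2 groups compared gave 2140 for NahG against coi1, 500 for ein2 against coi1 and 0 for stock in limma, where 1191 had an unadjusted p under 0.05 in the fit over all arrays. Camera with an estimated correlation gave 0 list shifts, and fry gave 8.

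Without a filter the counts were 3 for ein2, 37 for coi1, 43 for ein2 against coi1 and 0 for stock. Stage-lowered genes higher in NahG were then 121, those of ein2 0 and 0, those of coi1 16 and 3, and shared calls 0, 8 and 0 in the order above. With 1 added, stock gave 7, stage-raised genes lower in ein2 3 and the median of stage-lowered genes in NahG 0.455. With 64 added, stage-raised genes lower numbered 161 in NahG and 11 in ein2. Quantile normalization gave 5 stage-lowered genes higher in ein2, and 9 and 34 shared calls of NahG with ein2 and coi1.

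With the 25th percentile term the counts were 29 for ein2, 294 for coi1, 403 for ein2 against coi1 and 9 for stock, and stage-raised genes lower numbered 13 in ein2 and 105 in coi1, with 46 stage-lowered genes higher in coi1. With the 5S split they were 464 for NahG against coi1, 9 for ein2 against coi1 and 297 for stock, and stage-lowered genes higher numbered 113 in NahG, 1 in ein2 and 10 in coi1.

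Scaling to the hybridisation controls gave 424 for NahG, 47 for ein2, 409 for NahG against ein2 and 549 for NahG against coi1. RTE1 turned from -0.60 to 0.0669 in the stage comparison. Stage-lowered genes higher in NahG numbered 46 (median 0.477), those of ein2 32 lower and 0 higher (medians -0.41 and -0.041), and those of coi1 69 and 3. With the stage change from stock N933 alone the medians were -0.123 and 0.212 in NahG, -0.046 and 0.00884 in ein2 and -0.0751 and 0.116 in coi1. From stock N1644 alone they were -0.382 and 0.38 in NahG, -0.216 and 0.163 in ein2 and -0.249 and 0.34 in coi1.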

Other observations

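The groups in this part were formed by gene symbol, except the plastid genome, which was formed by chromosome, and no test here was chosen after its result was seen except scaling to the hybridisation controls.

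Of 69 plastid genome probe sets 36 fell with stage, 42 adjusted over the group alone, with a median of -0.98 (camera adjusted p = 5.12e-10; adjusted p = 0.557 with an estimated correlation), and the median was -0.20 when scaled to the hybridisation controls. In coi1 0 of the 69 passed in limma and the median was -0.27 (0.00124; 0.837 with an estimated correlation). Tubulin genes fell in 4 of 5 cases with stage (median -1.53, or -0.87 when scaled to the hybridisation controls; 0.0105; 0.557 with an estimated correlation), TUB5 by 2.18 ± 0.19, TUB1 by 1.56 ± 0.27, TUB7 by 1.53 ± 0.22 and TUB6 by 1.51 ± 0.20. WRKY genes rose with stage in 4 of 5 cases, though as a group they did not pass (0.102; 0.557 with an estimated correlation), and in NahG WRKY53 and ZAP1 fell, with a median of -0.47 (0.0245; 0.304 with an estimated correlation). Beta-glucosidase genes had a median of 0.51 in NahG (0.0245; 0.304 with an estimated correlation), with 4 of 12 higher, among them PYK10 at 1.77, and BGLU31 lower at -1.74.

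The stage 3.9 wild type arrays differed strongly at some genes. PDF1.2 had a mean of 722.0 ± 785 there (SD, n = 2), and leaving out either array lowered its adjusted p in ein2 from 0.142 to 0.0013 or 0.00128. The ein2 and coi1 arrays carry the same stock code, and JRG21 had means of 326.1 ± 111 and 6.49 ± 0.506 in them (SD, n = 2).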
